A study of Mus musculus with 24 samples.

How the data were processed

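Total RNA of mouse C2C12 cells, a myoblast line that can fuse into myotubes, was labelled with biotin and hybridised to oligonucleotide arrays. The titles give each culture a medium (GM or DM), a glucose concentration (5 or 25 mM), a replicate number from 1 to 3 and an array design (MA or MB). In this line GM and DM commonly stand for growth and differentiation medium, although the labels give only the abbreviations. The 24 arrays are 12 cultures on each of 2 designs, so each of the 4 groups has 3 cultures. Culture times, other medium components and the length of exposure to glucose are not stated.

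The deposited values are linear probe set intensities. How the authors made these intensities is not stated: no label, protocol or file header names software, a scaling target or a filter. The mean intensity after trimming 2 percent of values at each end was 149.984 to 149.988 on the MA arrays and 149.97 to 149.982 on the MB arrays. The arrays of a design had thus already been scaled to a common mean, and they were kept as deposited. Median intensities ran from 48.7 to 61.2 on MA and from 69.0 to 96.5 on MB. Between cultures of the same group, correlations across probe sets were 0.952 to 0.987 on MA and 0.797 to 0.919 on MB, and no pair of columns was identical. The number of arrays limits the precision.

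Intensities were used as log2 of the value plus a pseudocount of 20. Control probe sets, 64 on each design, were left out, and a probe set was tested when its mean over the 12 arrays lay above the 40th percentile of its design. This left 13575 of 22690 probe sets on MA, above an intensity of 33.2, and 13506 of 22575 on MB, above 54.1. Probe sets were joined to genes through the annotation provided for each design. On MA 20380 probe sets named one gene, 691 named several and 1555 named none, and on MB these numbers were 14661, 245 and 7605. The Entrez ID was found in the RefSeq annotation of GRCm38.p6 for 20351 probe sets on MA and 14486 on MB. Each gene was represented by its brightest tested probe set that named that gene alone, with MA preferred, which gave 12857 genes, 8127 on MA and 4730 on MB. Among 100 probe sets present on both designs, 10 of the 12 cultures had as best match on the other design the culture of the same title.

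Each design was fitted separately with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). The model had 4 group means over all 12 arrays and was moderated with eBayes with a trend, which left 8 residual degrees of freedom and added 6.22 prior degrees of freedom on MA and 10.1 on MB. There were 5 contrasts: DM against GM at 25 mM, DM against GM at 5 mM, 5 mM against 25 mM in GM, 5 mM against 25 mM in DM, and the interaction, which is the glucose change in DM minus that in GM. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within a design, and a probe set was called at an adjusted p under 0.05. Counts add both designs. Values are given as log2 change with its standard error (SE), or as group mean intensity with SD and n. The p-values measure only the spread between these samples.

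Before the data were examined, 25 gene lists were fixed, covering myogenic regulators, contractile apparatus, muscle excitation, fusion, inhibitors of differentiation, cell cycle, carbohydrate, lipid and mitochondrial metabolism, NAD and AMPK, stress responses, FoxO and autophagy, serum response, extracellular matrix, interferon response, ribosomal proteins and markers of other cell types. The tests, thresholds, alternative settings and rule for named genes were also fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 on the 8127 MA genes, with adjustment over 115 tests, 23 lists by 5 contrasts. The adipocyte list and the osteoblast list had fewer than 5 genes on MA and were not tested. Camera was repeated with a correlation estimated for each list, and limma's fry was run beside it, which asks whether the genes of a list move on balance in one direction. List medians are log2 changes over members on MA. Counts of members cover both designs, and were also taken adjusted over the list alone.

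The rule named 20 fixed genes, the 10 largest rises and 10 largest falls among called genes whose 3 cultures of one group all lay above the other 3, and up to 4 called members of each list, or the member with the smallest p where none was called. Non-overlap of 3 against 3 has a probability of 10 percent by chance. The rule gave more names than the text uses as examples. It favours the largest changes of the main fit. Shares of named genes that keep a call under an alternative therefore do not describe all called probe sets.

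Alternative settings fixed at that point were pseudocounts of 1 and 64, no filter and the 60th percentile, quantile normalization, median centring, eBayes without trend, only the arrays compared, array weights, the replicate number as a block, no probe sets of the _x_at or _s_at types, an intensity of at least 100 in one group mean, the mean of a gene's probe sets, the estimated correlation, and leaving out each culture. A batch seen in the 18S control probe set led to further alternatives, chosen after seeing the data: the batch as a block, the same with the estimated correlation, and the 8 high-18S cultures alone. All 5 contrasts can be fitted with the block. Other splits of the same cultures were counted, 10 for each comparison of 3 against 3 and 100 drawn with a fixed seed for the interaction.

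The procedure was tested on simulated data with the spread and the batch differences fitted here. For glucose in DM on MA, it called 56.7% of probe sets changed by log2 1 without the block and 88.1% with it, and 98.5% and 100% of those changed by log2 2. For glucose in GM on MA these shares were 55.2% and 71.6% at log2 1, and 95.5% and 98.5% at log2 2. At log2 0.5 in GM on MA they were 5.97% and 10.4%, and at log2 1 in GM on MB 8.96% and 19.4%. On MB in DM without the block, 4.48% were called at log2 1 and 50% at log2 2. In the list simulation, batch differences alone made camera call 6 of 110 unshifted list tests at the preset correlation, 3 of them among 22 tests for glucose in GM, and 0 with the estimated correlation or the block. Apart from the batch, probe sets were simulated as independent. The simulation therefore cannot show how often the preset correlation gives false calls where members of a list vary together, with or without the block.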

Results

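The arrays measured RNA levels in C2C12 cells, a mouse myoblast line, kept in GM or DM at 5 or 25 mM glucose. Each of the 4 groups had 3 cultures, and every culture was hybridised to both array designs. The series states that it asks whether calorie restriction affects how skeletal muscle precursors differentiate, and glucose is the nutrient that the labels name. DM against GM shows the change of medium at each glucose level, 5 mM against 25 mM shows the change of glucose in each medium, and the interaction tests whether the glucose change differs between the media. The number of arrays limits the precision.

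Control probe sets divided the cultures in a way that the labels do not explain. The control for 18S ribosomal RNA read 23.0 to 48.1 on MA in 4 cultures (GM_5mM-1, GM_5mM-2, DM_5mM-2 and DM_25mM-3, here called low-18S) and 279 to 1267 in the other 8, here called high-18S. On MB the ranges were 104 to 367 and 1582 to 5353, and the bacterial spike controls on MA read 266 to 339 and 598 to 1931 in the same cultures. Low-18S cultures were 2 of 3 in GM at 5 mM, 0 of 3 in GM at 25 mM and 1 of 3 in each DM group. The glucose comparison in DM is therefore even in this respect and the one in GM is not. The ratio of 3' to 5' control probe sets, a sign of RNA quality, also differed with the batch and the groups. For Gapdh on MB its log2 was -0.36 to -0.24 in the low-18S and -0.08 to 0.15 in the high-18S cultures. For Actb on MA it was 0.34 to 0.55 in GM at 25 mM, 0.12 to 0.18 in DM at 25 mM, 0.10 to 0.37 in DM at 5 mM, and -0.04, -0.05 and 0.38 in GM at 5 mM. Among the 8 high-18S cultures the 18S control also differed by medium, with 629 to 1267 in the 4 GM cultures and 279 to 501 in the 4 DM cultures. Results are given below with this batch as a block and within the 8 high-18S cultures, neither of which models these ratios.

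**Figure D1:**
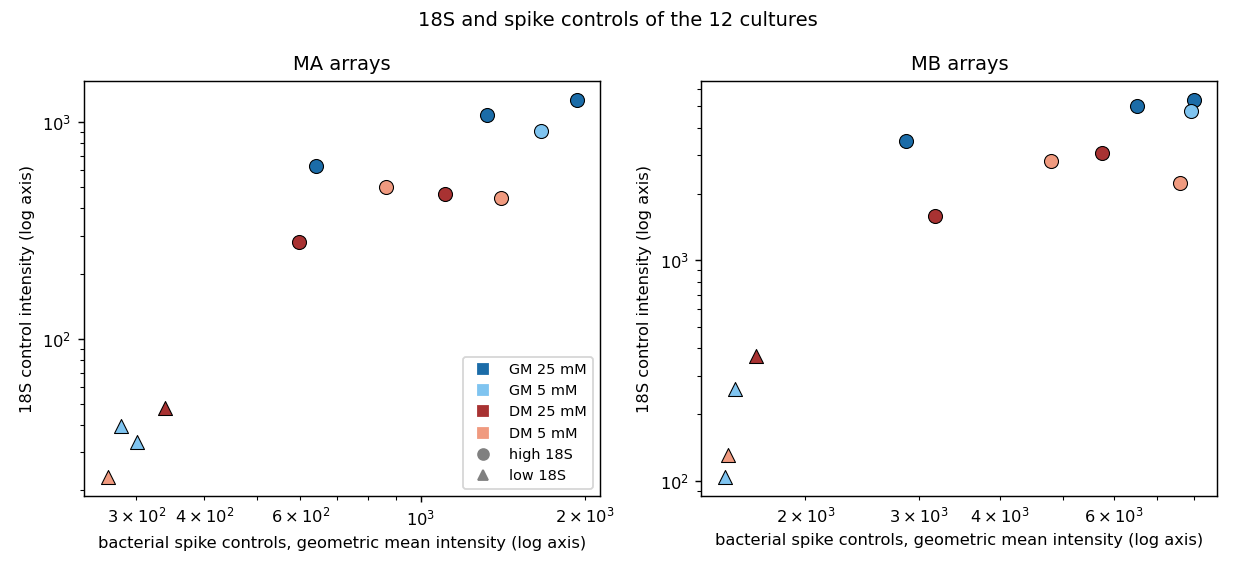
Intensity of the 18S control probe set against the geometric mean intensity of the bacterial spike controls, both on log axes, for the 12 cultures on the MA and the MB arrays, with colour for the group and shape for the batch. On MA the 4 low-18S cultures read 23.0 to 48.1 for 18S and the other 8 read 279 to 1267.

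At 25 mM glucose, genes of the muscle programme were far higher in DM than in GM. Myog, a transcription factor that drives muscle differentiation (Entrez 17928, chromosome 1, 134290004 to 134292548, GRCm38.p6), rose from an intensity of 14.8 ± 9.20 in GM to 6129 ± 1682 in DM (SD, n = 3 each), a log2 change of 7.45 (SE 0.26) with adjusted p = 4.67e-11. Skeletal muscle actin, Acta1, rose by log2 8.11 (SE 0.44), embryonic myosin heavy chain, Myh3, by 7.24 (SE 0.23), and muscle creatine kinase, Ckm, by 5.33 (SE 0.23). Genes of proliferation were lower in DM: Mki67, a marker of cycling cells, fell from 866 ± 137 to 278 ± 21.7 and Ccnd1, which encodes cyclin D1, from 736 ± 124 to 116 ± 30.4. Myod1, which marks the myoblast lineage, had a log2 difference of 0.30 (SE 0.14) and did not pass the test (adjusted p = 0.102).

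The contractile apparatus list rose as a group at 25 mM. Of its 41 measured members 40 rose and 0 fell, with a median log2 change of 4.19 and adjusted p = 2.45e-40 (0.0186 with an estimated correlation). The largest rises included Tnnc2, a troponin C of fast muscle, at 8.17 (SE 0.24) and Myl1, a myosin light chain, at 8.01 (SE 0.20). Of 25 genes of muscle excitation and calcium handling 22 rose and 0 fell (median 2.52, adjusted p = 7.55e-20). Examples were Mb, which encodes myoglobin, at 7.83 (SE 0.25) and Casq2, a calcium store protein, at 6.27 (SE 0.30). Among 18 myogenic regulators 13 rose and 1 fell (median 2.14, adjusted p = 2.82e-09), with the cell cycle inhibitors Cdkn1a at 3.24 (SE 0.23) and Cdkn1c at 5.60 (SE 0.19) and the transcription factor Mef2c at 3.09 (SE 0.27). The fusion list had 13 of 22 members higher and 5 lower (median 0.71, adjusted p = 0.000163), with Mymk and Mymx, the muscle fusogens, at 6.93 (SE 0.22) and 4.76 (SE 0.35). Its adjusted p = 0.0860 with an estimated correlation, so that this call is lost. Members that fell in these lists, named after their values were seen, were the regulator Hdac5 (-0.65) and the fusion genes Cd9 (-1.70), Dock1 (-0.62), Ehd2 (-1.23), Myof (-0.90) and Rac1 (-0.48).

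The cell cycle list fell, with 38 of 47 members lower and 0 higher, a median of -1.06 and adjusted p = 8.38e-15 (0.0866 with an estimated correlation, where the call is lost). Ube2c and Ccnb2, both of mitosis, changed by -2.12 (SE 0.13) and -1.94 (SE 0.13), and Tk1, of DNA synthesis, by -1.95 (SE 0.19). In the oxidative phosphorylation list 22 of 53 genes rose and 0 fell (median 0.31, adjusted p = 1.59e-07, and 0.458 with an estimated correlation), led by the muscle subunits of cytochrome oxidase Cox6a2 at 3.21 (SE 0.19) and Cox8b at 2.44 (SE 0.24). With the batch as a block 45 of them rose. In the list of the TCA cycle and pyruvate dehydrogenase 12 of 24 rose and 1 fell (median 0.47, adjusted p = 0.00275, and 0.0758 with an estimated correlation), with Pdk2, a kinase that inhibits pyruvate dehydrogenase, at 1.59 (SE 0.27). Of 30 genes of cholesterol and fatty acid synthesis 13 rose and 2 fell (median 0.39, adjusted p = 0.00327), among them Msmo1, of sterol synthesis, at 1.83 (SE 0.25) and Idi1, of isoprenoid synthesis, at 1.16 (SE 0.13). The members that fell, named after their values were seen, were Idh2 of the TCA cycle (-0.48) and Elovl6 (-0.54) and Fads1 (-0.76) of fatty acid synthesis.

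The shifts of the other lists did not pass the test at 25 mM with limma's camera at the preset correlation, and most had members that moved both ways. Among 28 inhibitors of myogenic differentiation 8 rose and 11 fell. Id1 and Id3, which block MyoD family proteins, fell by 1.83 and 2.80 on the log2 scale, whereas the Notch pathway repressor Hey1 rose by 2.28 (SE 0.22). In glycolysis and glucose uptake 4 of 22 rose and 9 fell. The muscle isoforms Pgam2 and Pfkm rose by 4.35 (SE 0.20) and 2.15 (SE 0.14), while the platelet isoform Pfkp changed by -1.07 (SE 0.15) and the glucose transporter Slc2a1 by -0.78 (SE 0.16). The pentose phosphate, hexosamine and glycogen list had 5 of 21 higher and 5 lower, with muscle glycogen phosphorylase, Pygm, at 4.48 (SE 0.25) and the pentose phosphate enzyme Tkt at -1.63 (SE 0.17). Of 35 extracellular matrix genes 9 rose, such as Postn at 2.78 (SE 0.23), and 10 fell, such as Lox at -2.32 (SE 0.15). The serum and immediate early list had 4 of 26 higher and 9 lower, with Egr1 at -1.69 (SE 0.14) and Fosl1 at -2.21 (SE 0.26). Higher and lower numbers were 3 and 4 of 16 for glucose-responsive transcription, 6 and 2 of 25 for NAD, sirtuin and AMPK, 4 and 10 of 27 for fatty acid oxidation, and 7 and 10 of 30 for FoxO, autophagy and atrophy. They were 9 and 3 of 26 for the unfolded protein response, 14 and 5 of 35 for ATF4 and amino acids, 4 and 7 of 22 for hypoxia, 2 and 3 of 14 for interferon, and 0 and 1 of 30 for ribosomal proteins. Blocking on the batch, 2 of these lists shifted up, ATF4 and amino acids (median 0.33, adjusted p = 0.0227, and 0.290 with an estimated correlation) and the unfolded protein response (0.16, 0.0440 and 0.207). Within the high-18S cultures their adjusted p was 0.0174 and 0.0432. Fry called 16 lists where camera called 8, among the others FoxO, autophagy and atrophy (lower, adjusted p = 0.000839) and the serum list (lower, 0.000425). Markers of other cell types, of which 1 in the adipocyte list is shared with another list, included 2 of 4 adipocyte genes lower (Cebpa at -1.91 (SE 0.20) and Lpl at -1.13 (SE 0.20)), 0 of 4 osteoblast genes called, and 1 of 5 blood and endothelial genes lower (Cd14 at -1.51 (SE 0.23)).

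The largest falls among probe sets called at 25 mM were those of Mgp, an inhibitor of calcification, at -4.65 (SE 0.18), Epha1, an ephrin receptor, at -4.05 (SE 0.16) and Grem1, a BMP antagonist, at -3.68 (SE 0.23). In all, limma called 5730 of 27081 probe sets, 2637 higher and 3093 lower, of which 1297 and 1144 changed at least 2-fold; 4794 were on MA and 936 on MB. With the batch as a block 6844 were called, and within the 8 high-18S cultures 5331. Of the 108 named genes called here, 108 stayed called with the block and 106 within the high-18S cultures, all in the same direction. Many muscle genes lay near background in GM, so that their log2 changes depend on the pseudocount, with Acta1 between 6.88 and 9.92 across the alternatives. The share of higher probe sets among those called went from 46.0% to 55.3% with median centring.

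At 5 mM glucose the same comparison again showed muscle genes higher and proliferation genes lower in DM. Myog rose from 20.6 ± 5.61 to 6250.0 ± 1993 (SD, n = 3 each), a log2 change of 7.22 (SE 0.26) with adjusted p = 8.24e-11, and Acta1 rose by 7.75 (SE 0.44). Mki67 fell from 932 ± 58.7 to 138 ± 9.40 and the mitosis genes Ube2c and Cenpa changed by -3.37 (SE 0.13) and -3.10 (SE 0.17). Hspa5, an endoplasmic reticulum chaperone (Entrez 14828, chromosome 2, 34772090 to 34776529, GRCm38.p6), fell from 2155 ± 148 to 1008 ± 115, a change of -1.09 (SE 0.16) with adjusted p = 0.000105, whereas at 25 mM it rose by 0.60 (SE 0.16) with adjusted p = 0.00866.

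At 5 mM glucose, 39 of 41 contractile genes rose and 0 fell (median 3.78, adjusted p = 9.33e-40), with Mylpf, a myosin light chain, at 8.02 (SE 0.26). In muscle excitation 20 of 25 rose (median 2.59, adjusted p = 1.43e-17), with Mb at 6.07 (SE 0.25), and among myogenic regulators 13 of 18 rose and 1 fell (median 2.12, adjusted p = 2.43e-09). The fusion list had 10 higher and 5 lower (median 0.48, adjusted p = 0.000574, and 0.101 with an estimated correlation). In the cell cycle list 32 of 47 fell and 0 rose (median -1.52, adjusted p = 8.17e-16, and 0.0819 with an estimated correlation). Of 30 genes of cholesterol and fatty acid synthesis 18 rose and 0 fell (median 0.79, adjusted p = 1.12e-08), with Msmo1 at 2.41 (SE 0.25) and Hmgcs1, the enzyme that makes HMG-CoA, at 1.62 (SE 0.19). The oxidative phosphorylation list had 11 of 53 higher and 0 lower (median 0.20, adjusted p = 0.000783, and 0.654 with an estimated correlation), and a median of 0.06 with the block. In the list of fatty acid oxidation and PPAR targets 11 of 27 fell and 1 rose (median -0.33, adjusted p = 0.0318, and 0.458 with an estimated correlation). Those lower included Cpt1a, which admits fatty acids to mitochondria, at -1.81 (SE 0.14) and Plin2, a lipid droplet coat protein, at -2.12 (SE 0.15), and the range of this list's adjusted p over the alternatives was 0.0118 to 0.458, the call being lost also without DM_5mM-2 (0.0693). Blocking on the batch, the unfolded protein response also shifted up (median 0.33, adjusted p = 0.0383, and 0.200 with an estimated correlation) and the matrix list down (-0.42, 0.0463 and 0.208). Fry called 14 lists at 5 mM where camera called 8, among the others the serum list (lower, adjusted p = 4.75e-05).

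**Figure D2:**
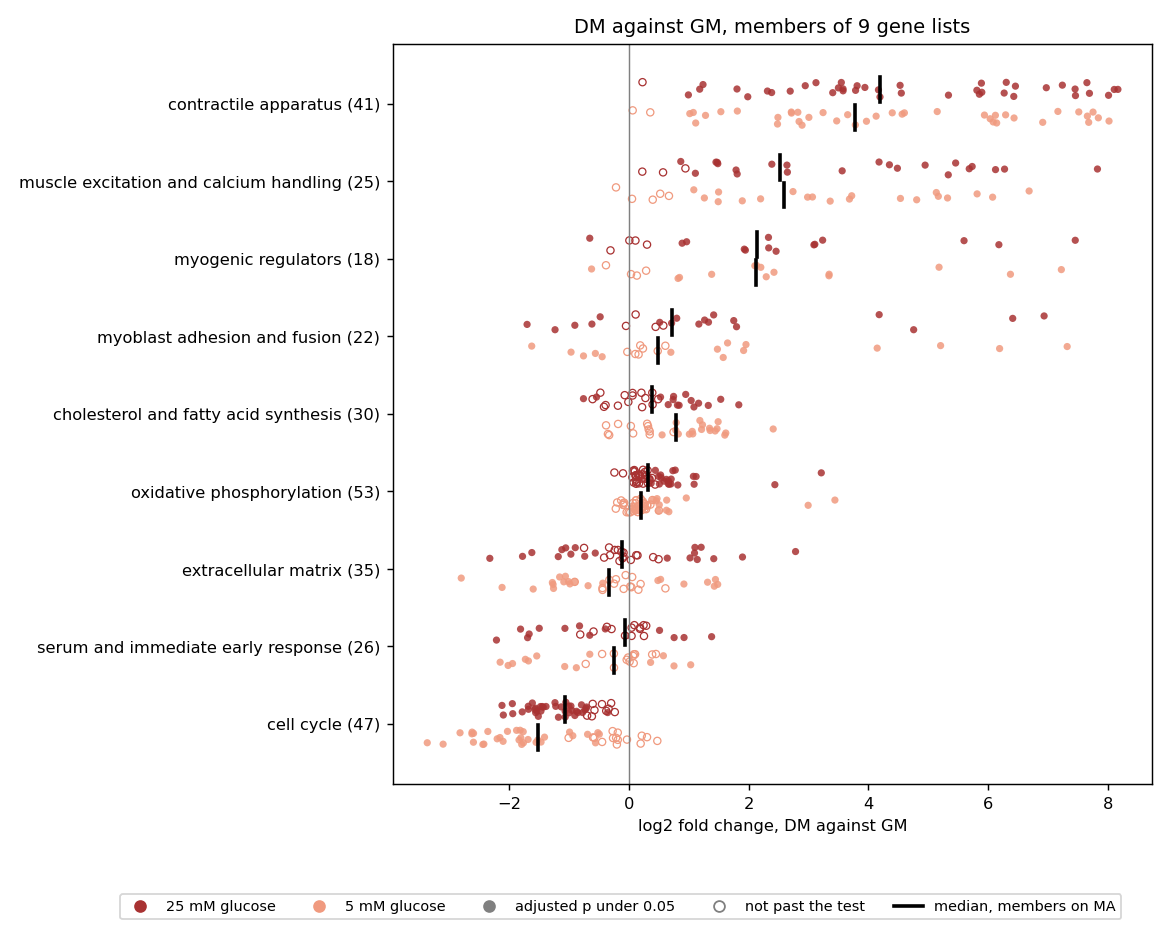
Log2 fold change of DM against GM for each measured member of 9 gene lists at 25 mM and at 5 mM glucose, with filled points for adjusted p under 0.05, open points for members that did not pass, black bars for medians over members on MA, and numbers of measured members in parentheses. The medians of the contractile list are 4.19 and 3.78, and those of the cell cycle list -1.06 and -1.52.

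At 5 mM limma called 4728 of 27081 probe sets, 2022 higher and 2706 lower, of which 968 and 1179 changed at least 2-fold; 3894 were on MA and 834 on MB. With the batch as a block 5898 were called, and within the 8 high-18S cultures, where GM at 5 mM has 1 culture whose spread is taken from the other groups, 2789. Median centring took the balance to 2267 higher and 2204 lower, or from 42.8% to 50.7% higher. Of the 100 named genes called here 99 stayed called with the block and 93 within the high-18S cultures, all in the same direction. Across 8127 genes, which are not independent replicates, the changes at 25 mM and at 5 mM had Pearson r = 0.87 and Spearman rho = 0.713. Genes called in both comparisons were 811 higher in both, 1142 lower in both and 7 in opposite directions, against 161 and 346 in both by chance.

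Lower glucose in GM was tested for a response of cells in that medium. A single gene was called: Mgll, monoacylglycerol lipase, which cleaves monoacylglycerols (Entrez 23945, chromosome 6, 88724412 to 88828360, GRCm38.p6), rose from 11.5 ± 2.87 at 25 mM to 62.3 ± 8.22 at 5 mM (SD, n = 3 each), a log2 change of 1.39 (SE 0.16) with adjusted p = 0.00615. Txnip, whose transcription is known to follow glucose, read 220.3 ± 46.3 at 25 mM and 77.0 ± 11.1 at 5 mM, a difference of -1.30 (SE 0.25) that did not pass the test (adjusted p = 0.271). Nor did Myog, with a difference of 0.24 (SE 0.26), Mki67, with 0.11 (SE 0.13), and Hspa5, with 0.06 (SE 0.16).

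No member of any list was called in GM by limma with adjustment over all probe sets. With the preset correlation 5 lists shifted: TCA cycle and pyruvate dehydrogenase (median 0.10, adjusted p = 0.0216), ATF4 and amino acids (-0.21, adjusted p = 0.00350), hypoxia (0.18, adjusted p = 0.0460), contractile apparatus (-0.19, adjusted p = 0.0468) and ribosomal proteins (-0.24, adjusted p = 0.0156). None kept its call with an estimated correlation, where the adjusted p was 0.137, 0.243, 0.239, 0.692 and 0.692 in that order. The contractile and ribosomal medians changed sign with the batch as a block, to 0.09 (adjusted p = 0.161) and 0.11 (adjusted p = 0.000372, and 0.422 with an estimated correlation), and the latter also with quantile normalization. Hypoxia went to 0.04 with the block and lost its call (adjusted p = 0.288). ATF4 went to -0.07 (adjusted p = 0.0397, and 0.36 with an estimated correlation) and the TCA cycle to 0.08 (0.0256 and 0.225). Over the alternatives the adjusted p ranged from 0.000805 to 0.692 for the contractile list, 3.67e-05 to 0.692 for ribosomal proteins, 0.0121 to 0.575 for hypoxia, 0.000154 to 0.36 for ATF4 and 0.00215 to 0.225 for the TCA cycle. With the block 2 further lists shifted up in GM, oxidative phosphorylation (median from -0.04 to 0.15, adjusted p = 2.07e-11, and 0.0789 with an estimated correlation) and cholesterol synthesis (from 0.07 to 0.11, adjusted p = 0.0203, and 0.0912). Within the high-18S cultures their adjusted p was 2.48e-05 and 0.0406. Fry called 3 lists in GM. Single cultures also ended each call made without the block. That of the contractile list was lost without GM_25mM-1 (0.0740), GM_25mM-2 (0.0673), GM_25mM-3 (0.0649) or GM_5mM-1 (0.232). That of the ribosomal list was lost without GM_25mM-1 (0.0563), GM_25mM-2 (0.0854), GM_5mM-1 (0.182) or GM_5mM-2 (0.175). Hypoxia lost it without GM_25mM-1 (0.221), GM_25mM-2 (0.0514) or GM_5mM-2 (0.124), the TCA cycle without GM_25mM-2 (0.0673) or GM_5mM-3 (0.0592), and ATF4 without GM_25mM-1 (0.0611).

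Limma called 1 of 27081 probe sets in GM, higher at 5 mM, while 2398 had an unadjusted p under 0.05. With the block the count was 1 (1641 unadjusted) and the log2 difference of Mgll was 1.30 (adjusted p = 0.0170), and within the high-18S cultures limma called 0 (1085 unadjusted) and that of Mgll was 1.23 (adjusted p = 0.440). Across the alternatives the adjusted p of Mgll ranged from 0.000287 to 0.440, and it was not called in 5 of 19, among them those without GM_5mM-1 (0.0888) or GM_5mM-2 (0.0668). The count was 0 (limma, 3 cultures against 2) without either of these, 2 without GM_25mM-2 or without GM_25mM-3 and 5 without GM_5mM-3, and array weights gave 815. Median centring moved the median of all MB probe sets by 0.110 in this comparison and by -0.108 in the interaction.

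Lower glucose in DM was tested for its effect on cells in the differentiation setting, which bears most directly on the stated question. Several muscle genes were lower at 5 mM: Mss51, a gene of skeletal muscle (Entrez 74843, chromosome 14, 20482857 to 20496901, GRCm38.p6), fell from 1698 ± 225 to 159 ± 74.1 (SD, n = 3 each), a log2 change of -3.36 (SE 0.37) with adjusted p = 0.000211, and Mb fell from 5905 ± 1204 to 1881 ± 389.9. Hspa5 fell from 3140.4 ± 233 to 1008 ± 115, a change of -1.62 (SE 0.16) with adjusted p = 0.000137, whereas Pdia3, a protein disulfide isomerase of the same compartment, rose from 1294 ± 168 to 2650.1 ± 309. The largest rise was that of Aldh1l2, a mitochondrial enzyme of folate metabolism, from 522 ± 62.5 to 2542 ± 617. The regulators Myog, with a difference of 0.01 (SE 0.26), Myod1, with 0.02 (SE 0.14), and Cdkn1a, with -0.19 (SE 0.23), did not pass the test.

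The contractile list shifted down, with a median of -0.42 and adjusted p = 1.16e-14. Of its 41 members 8 fell, 0 rose and 33 did not pass, and adjusted over the list alone 16 fell. The falls included Actn2, an actinin of the sarcomere, at -1.64 (SE 0.20) and the perinatal myosin heavy chain Myh8 at -1.32 (SE 0.23), while Acta1, at -0.32 (SE 0.44), and Ckm, at -0.62 (SE 0.23), did not pass. The call is lost at an adjusted p = 0.121 with an estimated correlation, and with the block as well that value is 0.0169, within a range over the alternatives of 6.13e-19 to 0.121. The list's median was -0.38 in the high-18S and -0.38 in the low-18S cultures, the latter being 1 culture against 1. In muscle excitation and calcium handling 2 of 25 fell, Mb at -1.64 (SE 0.25) and the muscle phosphoglycerate mutase Pgam2 at -1.49 (SE 0.20), and 8 adjusted over the list alone (median -0.37, adjusted p = 5.15e-07). Among regulators Mef2c fell by 1.35 on the log2 scale (adjusted p = 0.0202), a call lost without DM_25mM-1 (0.0985), DM_25mM-2 (0.0795), DM_5mM-1 (0.0522) or DM_5mM-3 (0.113), and the fusion gene Itgb1bp2, which encodes melusin, changed by -1.41 (SE 0.17).

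Extracellular matrix genes were lower at 5 mM in DM, with 7 of 35 members lower and 0 higher (12 and 1 adjusted over the list alone), a median of -0.32 and adjusted p = 6.51e-09. They included the basement membrane collagen Col4a2 at -0.94 (SE 0.11) and Tnc, tenascin C, at -0.90 (SE 0.12). Cholesterol and fatty acid synthesis moved the other way, with a median of 0.51 and adjusted p = 7.94e-18. Of its 30 members 2 rose, Fdft1, which makes squalene, at 0.77 (SE 0.12) and Idi1, of isoprenoid synthesis, at 0.60 (SE 0.13), and 18 rose adjusted over the list alone. The call of Idi1 was lost without DM_25mM-1 (0.0668), DM_25mM-2 (0.136), DM_5mM-1 (0.0567), DM_5mM-2 (0.0671) or DM_5mM-3 (0.129). The list medians were 0.52 in the high-18S and 0.49 in the low-18S cultures for cholesterol synthesis, and -0.35 and -0.29 for the matrix. The low-18S values compare 1 culture with 1. Both lists and that of muscle excitation kept their call with an estimated correlation (0.000907, 0.00516 and 0.0231).

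Cell cycle genes went both ways in DM. Of 47 measured 11 were lower and 2 higher at 5 mM (19 and 9 adjusted over the list alone), with a median of -0.33 and adjusted p = 0.00201 (0.492 with an estimated correlation). The members that fell included Cenpa at -1.31 (SE 0.17), Ube2c at -1.29 (SE 0.13) and Mki67 at -0.92 (SE 0.13), whereas the 2 members that rose were E2f1, a transcription factor of the entry into DNA synthesis, at 1.07 (SE 0.17) and, named after its value was seen, Cdt1 (0.89). Ccnd1, which is not in this list, rose from 116 ± 30.4 to 256 ± 49.0, the call of Ccnd1 being lost without DM_5mM-3 (0.0702).

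Stress and metabolic lists held smaller shifts. The unfolded protein response list did not shift (median 0.21, adjusted p = 0.398) while its members went both ways. Of 26 measured 3 fell, Hspa5, Manf at -1.36 (SE 0.13) and Creld2 at -1.64 (SE 0.21). Another 3, which encode folding proteins, rose, Pdia3 at 1.02 (SE 0.13) and, named after their values were seen, Dnajb11 (0.96) and Pdia6 (0.83). The list of ATF4 and amino acids shifted down (median -0.25, adjusted p = 0.000330, and 0.166 with an estimated correlation). Of its 35 members 4 fell, such as Cars, a cysteine tRNA ligase, at -1.15 (SE 0.15) and Aldh18a1, of proline synthesis, at -0.85 (SE 0.15). Another 2 rose, such as Phgdh, of serine synthesis, at 0.92 (SE 0.17), a call lost without DM_5mM-1 (0.0567) or DM_5mM-3 (0.0572). Oxidative phosphorylation had a median of -0.19 (adjusted p = 1.69e-05, and 0.530 with an estimated correlation), with 0 of 53 members called and 46 below 0. This call was lost without DM_5mM-2 (0.103), and its adjusted p ranged from 1.57e-09 to 0.530 over the alternatives. The TCA cycle list (median -0.12, adjusted p = 0.00707, and 0.0956 with an estimated correlation) had 0 of 24 called. Fatty acid oxidation (median -0.10, adjusted p = 0.0216, and 0.420 with an estimated correlation) had 1 of 27 lower, Etfa at -0.54 (SE 0.11). The call of Etfa was lost without DM_25mM-1 (0.107), DM_25mM-2 (0.107), DM_5mM-1 (0.0872), DM_5mM-2 (0.0571) or DM_5mM-3 (0.0643). The serum list (median -0.15, adjusted p = 0.0216, and 0.206 with an estimated correlation) had 2 of 26 lower, among them the growth factor Ccn2 at -1.56 (SE 0.20), and 1 higher, Nr4a1 at 0.73 (SE 0.17). The call of Nr4a1 was lost without DM_25mM-1 (0.123), DM_25mM-2 (0.130), DM_25mM-3 (0.143), DM_5mM-1 (0.143), DM_5mM-2 (0.128) or DM_5mM-3 (0.126). Within the high-18S cultures the serum list (adjusted p = 0.30) and fatty acid oxidation (0.0938) lost their calls. The interferon list shifted up (median 0.30, adjusted p = 0.0216, and 0.234 with an estimated correlation) with 0 of 14 called. Of these 4 lists each lost its call without some single culture: the TCA cycle without DM_5mM-1 (0.0861), fatty acid oxidation without DM_25mM-2 (0.101), DM_5mM-1 (0.0538) or DM_5mM-2 (0.200), and the serum list without DM_25mM-3 (0.198) or DM_5mM-2 (0.0628). Interferon lost it without DM_25mM-3 (0.0712) or DM_5mM-1 (0.110). The ribosomal list shifted up with the batch as a block (median 0.15, adjusted p = 0.000121, and 0.422 with an estimated correlation). Fry called 8 lists in DM where camera called 11. Lists that did not shift held single called genes such as Pfkm, the muscle phosphofructokinase, at -0.97 (SE 0.14). Of the markers of other cell types limma called no member in DM.

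**Figure D3:**
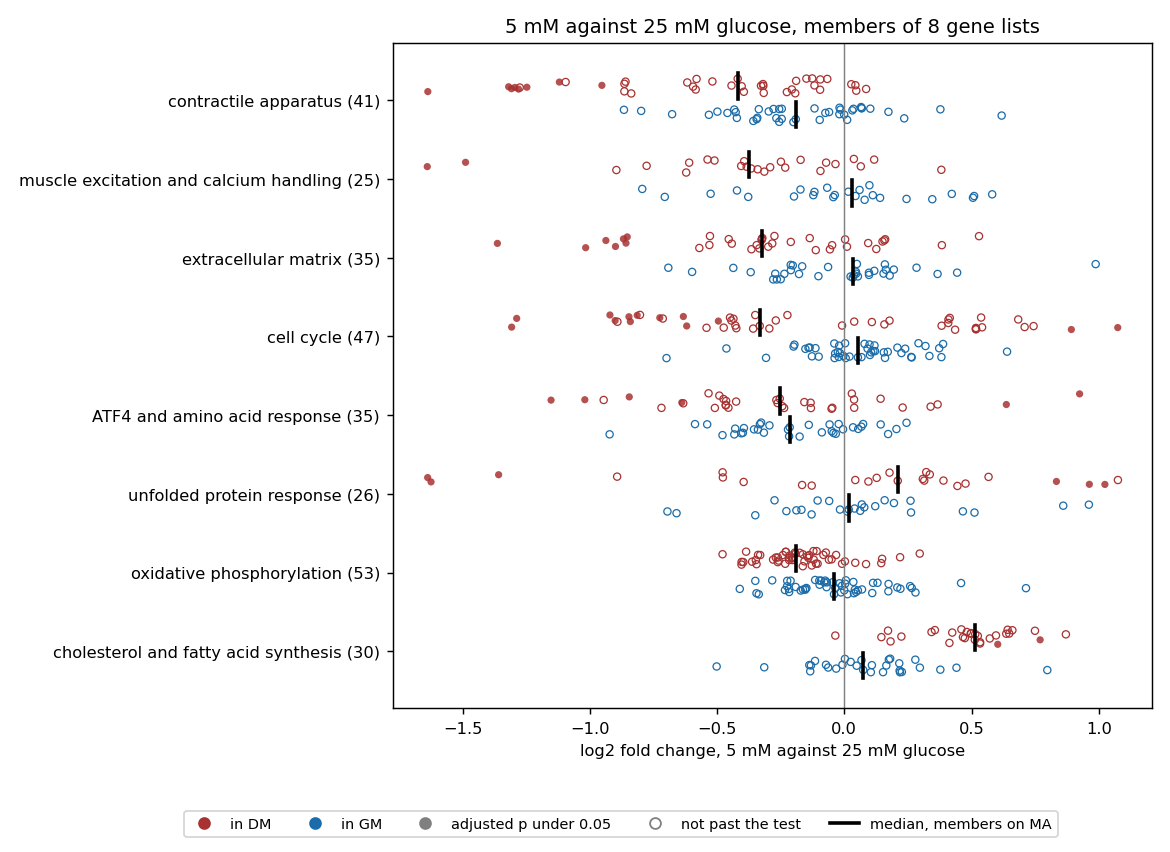
Log2 fold change of 5 mM against 25 mM glucose for each measured member of 8 gene lists, in DM and in GM, with filled points for adjusted p under 0.05, open points for members that did not pass, black bars for medians over members on MA, and numbers of measured members in parentheses. In DM the cholesterol list has a median of 0.51 and the contractile list one of -0.42, and in GM no member is called.

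In DM limma called 231 of 27081 probe sets, 86 higher and 145 lower at 5 mM, of which 21 and 62 changed at least 2-fold; 222 were on MA and 9 on MB, and 2179 had an unadjusted p under 0.05. With the batch as a block 607 were called (278 higher, 329 lower), and within the high-18S cultures 162 (65 higher, 97 lower). Of the 55 named genes called here 55 stayed called with the block and 45 within the high-18S cultures, all in the same direction. With the block the direction could not change, since the DM groups are even in the batch and each log2 change stays as it was. Of these 55 calls 38 held without each culture in turn. The count was 131 without DM_25mM-1, 144 without DM_25mM-2, 137 without DM_5mM-1 and 139 without DM_5mM-3, and 109 with only the 6 compared arrays.

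**Figure D4:**
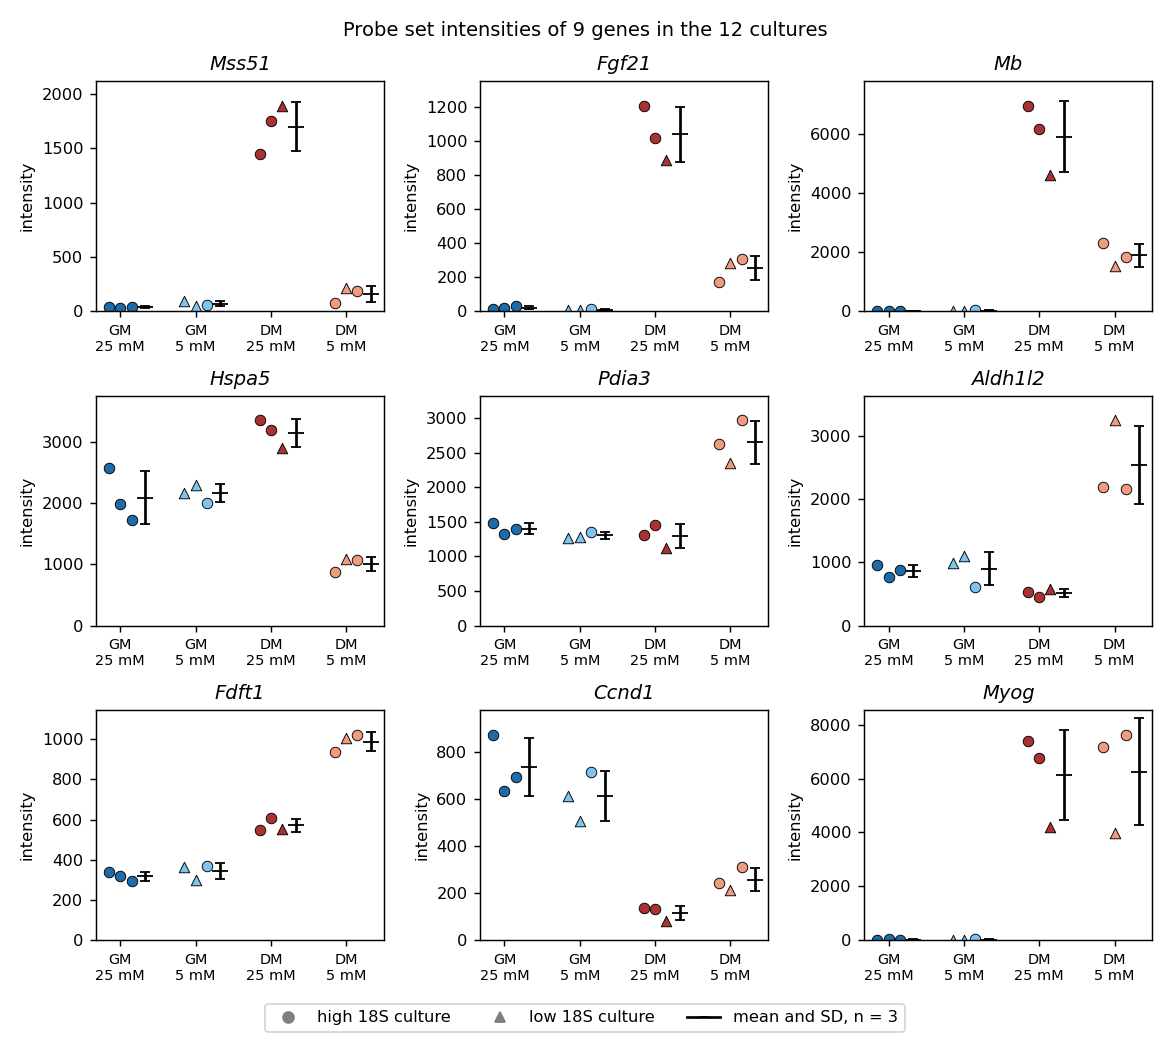
Probe set intensity of 9 genes in each of the 12 cultures, with circles for high-18S and triangles for low-18S cultures and bars for the mean and SD of 3 cultures in each group. Mss51 reads 1698 ± 225 in DM at 25 mM and 159 ± 74.1 at 5 mM, whereas Myog reads 6129 ± 1682 and 6250.0 ± 1993.

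Whether glucose acted differently in the 2 media was tested as the interaction, the log2 change of 5 mM against 25 mM in DM minus that in GM. Mss51 had the largest interaction, -4.01 (SE 0.52) with adjusted p = 0.00503, with 33.9 ± 7.71 and 65.8 ± 22.1 in GM at 25 and 5 mM. Hspa5 had -1.69 (SE 0.22) (adjusted p = 0.00769) and Aldh1l2 2.20 (SE 0.31) (adjusted p = 0.0102, and lost without GM_25mM-1 (0.0668)). The mitosis gene Ube2c had -1.25 (SE 0.19), and the collagens Col1a1 and Col4a2 had -1.86 (SE 0.27) and -0.98 (SE 0.15). Several muscle genes with a fall in DM lay near background in GM, where little room is left for a fall, such as Actn2 at 8.37 ± 0.90 and 3.57 ± 0.34. The same limit holds for interactions of the contractile and excitation lists, since many muscle genes lay near background in GM.

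By lists, the interaction of cholesterol and fatty acid synthesis was above 0 (median 0.40, adjusted p = 1.59e-07) with 0 of 30 members called, and the contractile list lay below 0 (-0.33, adjusted p = 2.27e-05, and 0.420 with an estimated correlation) with 1 of 41 called. The matrix list (-0.16, adjusted p = 0.000161) had 4 of 35 lower and the cell cycle list (-0.29, adjusted p = 0.00225, and 0.493 with an estimated correlation) 6 of 47 lower and 1 higher. Of 10 lists called, cholesterol, matrix and TCA cycle (-0.37) kept the call with an estimated correlation (0.00489, 0.0368 and 0.0455). The block changes which lists hold: with block and estimated correlation the TCA cycle lost its call (0.0757), and the contractile list (0.0170), excitation (0.0109) and oxidative phosphorylation (0.0318) passed beside cholesterol and matrix. With the block at the preset correlation glycolysis (from 0.15, adjusted p = 0.833, to -0.12, adjusted p = 0.0481, and 0.138 with an estimated correlation) and fatty acid oxidation (-0.18, 0.0227 and 0.429) were also called. Fry called 6 lists. Limma called 75 of 27081 probe sets, 23 above and 52 below 0, with 71 on MA and 4 on MB, and 2485 had an unadjusted p under 0.05. With the batch as a block 130 were called, and within the high-18S cultures 17. Of the 35 named genes called here 34 stayed called with the block, 18 with the replicate number as a block and 8 within the high-18S cultures, all in the same direction. The count fell to 26 without GM_5mM-1, 32 without GM_5mM-2, 35 without GM_25mM-1, 42 without GM_25mM-2, 30 without DM_25mM-1, 30 without DM_25mM-2, 35 without DM_5mM-1 and 40 without DM_5mM-3.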

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

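Of the tests below, those of the 18S batch, of a stronger response to DM and of myoblasts were chosen only after the result was seen. Groups of 3 cultures are too small for a test of single outlying samples, and none was made.

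Genes and lists follow for which the glucose change in DM differed from that in GM by a test of the interaction. With limma it was past the test for 75 probe sets, and the values are log2 changes in DM minus those in GM. Genes of muscle below 0 were Mss51 at -4.01, Mb at -1.75, Actn2 and Pgam2 at -1.37 each, Itgb1bp2 at -1.20 and Pfkm at -1.07. Some of these lay near background in GM, such as Actn2 and Mb, the latter at 1.85 to 25.1 in the GM cultures. Little room is left there for a fall, so that their interaction mostly repeats the change in DM. Genes of the matrix below 0 were Col1a1 at -1.86, Col4a1 at -1.05, Tnc at -1.02 and Col4a2 at -0.98, with Cilp at -2.39 and Olfml3 at -1.67. Cell cycle genes below 0 were Cenpa at -1.43, Bub1 at -1.35, Ube2c at -1.25, Bub1b at -1.11 and Mki67 at -1.04. Genes of the endoplasmic reticulum were Herpud1 at -1.85, Hspa5 at -1.69 and Manf at -1.34, and Pdia3 at 1.13. Others below 0 were Il17b at -1.87, Ccn2 at -1.83, Dtd1 at -1.67 and Bhlhe40 at -1.53. Above 0 were Aldh1l2 at 2.20, Kcnk13 at 1.94, Slc41a3 at 1.78, Lgals3bp at 1.59, Nucb2 at 1.49, Phgdh at 1.32, Nucb1 at 1.20, Basp1 at 1.17, and Anxa3 and Ifitm3 at 1.15 each.

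Of these 35 genes 34 stayed called with the batch as a block, but 18 with the replicate number as a block and 8 within the high-18S cultures. Of the 35, 11 kept their call without each of the 12 cultures in turn: Hspa5, Kcnk13, Anxa3, Mss51, Il17b, Col1a1, Ccn2, Olfml3, Ube2c, Manf and Col4a2. A single culture ended the call of Aldh1l2, without GM_25mM-1 (0.0668), of Lgals3bp, without GM_5mM-1 (0.0606), of Tnc, without DM_25mM-2 (0.0589) or GM_5mM-2 (0.0596), of Cenpa, without DM_25mM-1 (0.0514), DM_25mM-2 (0.0553) or GM_25mM-1 (0.0529), and of Ifitm3, without DM_25mM-1 (0.0514), DM_25mM-2 (0.0522) or GM_5mM-1 (0.0567). The other 19 were lost without 4 to 11 of the cultures, with an adjusted p of at most 0.167 (Cilp). The count of 75 was 26 without GM_5mM-1, 30 without DM_25mM-1, 30 without DM_25mM-2, 32 without GM_5mM-2, 35 without GM_25mM-1, 35 without DM_5mM-1, 40 without DM_5mM-3 and 42 without GM_25mM-2.

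Lists with an interaction above 0 were cholesterol and fatty acid synthesis (median 0.40), interferon (0.43, adjusted p = 0.206 with an estimated correlation) and ribosomal proteins (0.39, 0.654). Lists below 0 were the contractile apparatus (-0.33, adjusted p = 0.420 with an estimated correlation), excitation and calcium handling (-0.43, 0.0966), the TCA cycle (-0.37), pentose phosphate and glycogen (-0.35, 0.120), cell cycle (-0.29, 0.493), matrix (-0.16) and oxidative phosphorylation (-0.11, 0.691). The batch as a block moved several of these medians: that of ribosomal proteins to 0.04 (adjusted p = 0.527) and within the high-18S cultures to 0.09 (0.108), so that this call is lost. It moved the contractile list to -0.66 (adjusted p = 1.03e-13), oxidative phosphorylation to -0.30 (4.71e-17), the TCA cycle to -0.22 (0.000170), the matrix to -0.27 (3.26e-07) and pentose phosphate to -0.25 (0.108, no longer called). Within the high-18S cultures the cell cycle (0.118), pentose phosphate (0.127) and interferon (0.115) lists were not called either. The adjusted p ranged over the alternatives from 0.00510 to 0.206 for interferon, 9.62e-06 to 0.879 for ribosomal proteins, 1.03e-13 to 0.420 for the contractile list and 3.86e-06 to 0.0966 for excitation. It ranged from 1.57e-05 to 0.0757 for the TCA cycle, 0.00914 to 0.211 for pentose phosphate, 4.13e-05 to 0.520 for cell cycle and 4.71e-17 to 0.691 for oxidative phosphorylation. Single cultures ended the calls of interferon, without GM_25mM-1 (0.0521), of pentose phosphate, without DM_25mM-3 (0.0616) or GM_25mM-1 (0.0531), and of oxidative phosphorylation, without DM_25mM-2 (0.0885), DM_5mM-2 (0.376) or GM_5mM-3 (0.122).

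Of 100 splits of the cultures, 2, the real one included, gave at least as many interaction probe sets as the real split (75, highest other 79). The 8 other splits that parted the DM cultures as labelled but regrouped those of GM gave a median of 45 and at most 79. The remaining 91 gave at most 14, so that the count follows the glucose groups in DM. The share of 2 in 100 therefore cannot decide whether chance in the GM grouping accounts for the interaction count. For lists adjusted over the 23 lists of one comparison the real interaction gave 11 and the highest other split 10, 1 of 100 being as large. The highest was 10 among the 8 splits with DM parted as labelled and 7 among the other 91. This share cannot decide about chance for the interaction either. With an estimated correlation the real split gave 3 lists, and so did the highest other, with 6 of 100 as large, so that chance is not excluded there either.

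The 18S control, which the comparisons do not use, separated the cultures, with 279 as the lowest intensity on MA among the 8 high-18S cultures and 48.1 as the highest among the 4 low-18S cultures. The labels give no processing date or batch, so what divided the cultures is not known from them.

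Almost no probe set was called for glucose in GM, 1 against 231 in DM. Probe sets with an unadjusted p under 0.05 (limma) numbered 2398 in GM and 2179 in DM, and 1641 and 3172 with the batch as a block. For single probe sets, the 18S batch hiding a broad response is argued against by a count of 1 with the batch as a block. This holds for many changes of log2 1 or more on MA, of which the simulation called 71.6% at log2 1 with the block. It does not hold for each single gene, since Txnip differed by more than log2 1 in GM and was not called. For smaller changes the count decides nothing, since 10.4% of those of log2 0.5 were called on MA. On MB 19.4% of those of log2 1 were called. DM cultures chosen to give a layout like that of GM gave 196 to 221 called with the block. This argues against too little power from the uneven layout for changes as large as those called in DM. It cannot decide for smaller ones. Noisy arrays, which array weights would set right, are argued against because weights gave 815 for the real split and 1646 for another split that put both low-18S GM cultures in one group. A weaker response of cells in GM, which the design names, stays open, tested only by the interaction given above.

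The list of cholesterol and fatty acid synthesis was higher at 5 mM than at 25 mM in DM, with a median of 0.51. The DM groups are even in the 18S batch, so that a batch difference equal in both groups cancels from this median by design. Within the 2 batches the medians were 0.52 in the high-18S and 0.49 in the low-18S cultures. They argue against a shift made by 1 batch alone, as far as 1 low-18S culture against 1 can show. The scaling between arrays is argued against by 0.512 with quantile normalization and 0.504 with median centring. A stronger response to DM at 5 mM that takes in the contractile list is argued against by the median of that list, -0.42. A response stronger only in part stays open. From 25 mM to 5 mM the DM against GM median went from -1.47 to -2.10 for genes of G2 and mitosis. For genes of G1 and S it went the other way, from -0.72 to -0.36. These phases were parted after the values were seen. An effect of glucose on the genes of cholesterol and fatty acid synthesis in DM may be put forward as a hypothesis, found and tested on the same data.

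The contractile list was lower at 5 mM in DM, with a median of -0.42. As for the cholesterol list, a batch difference equal in both DM groups cancels by design. The medians of -0.377 and -0.380 within the 2 batches argue against a shift made by 1 batch alone, as far as 1 low-18S culture against 1 can show. Myoblasts that cycle through mitosis in place of differentiated cells are argued against by a median of -0.62 for genes of mitosis, with an upper quartile of -0.44; the whole cell cycle list (median -0.33, members both ways) decided nothing, and its genes were parted after their values were seen. Myoblasts in G1 or S in place of differentiated cells stay open, since the G1 and S genes, also higher in GM, had a median of 0.43 and a lower quartile of 0.163, and Ccnd1 rose by 1.03, a call lost without DM_5mM-3 (0.0702). An even dilution of the RNA of differentiated cells was not decided. Of the genes raised most by DM 16.7%, or 7 of 42, lay over 2 SE from the set median of -0.31, 6 below and 1 above. The bound for arguing against it was over 20 percent. An even dilution alone would not give falls like those of Actn2 at -1.64 (SE 0.20) and Itgb1bp2 at -1.41 (SE 0.17) beside Myog at 0.01 (SE 0.26). An effect of glucose on differentiation, which the design names and which was not tested, stays open as well.

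For the simple comparisons 10 splits of 6 cultures exist, too few for a share under 0.05. For DM against GM the real split gave 5730 probe sets at 25 mM and the highest other 0 (1 of 10 splits as large), and at 5 mM 4728 and 1 (1 of 10). For glucose it gave 1 in GM and the highest other 5 (2 of 10), and 231 in DM and 2 (1 of 10). Lists adjusted over the 23 lists of one comparison numbered 8 against 10 at 25 mM (4 of 10), 8 against 8 at 5 mM (2 of 10), 1 against 4 in GM (9 of 10) and 11 against 10 in DM (1 of 10). With an estimated correlation they numbered 7 against 0 (1 of 10), 4 against 0 (1 of 10), 0 against 0 (10 of 10) and 3 against 0 (1 of 10) in the same order. In GM the 3 other splits that put both low-18S cultures in one group gave 1417 to 1646 with array weights. The other 6 gave 0 to 1. The count with weights thus follows these 2 cultures, which share 5 mM glucose as well as the batch.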

How the results depend on the processing

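The batch as a block and the fit within the 8 high-18S cultures were chosen after seeing the data. Gene values here are those of genes picked by the rule for named genes, which favours the largest changes. Of 8334 such values under the alternatives 7784 kept direction and side of the threshold, and 421 were weaker and 53 newly past it. Another 76 that passed under neither setting changed sign, and no called value reversed. Of 1016 list values 884 were the same, 126 weaker and 6 reversed. The cause of the changes below was not tested, except that fewer cultures or probe sets give less power.

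DM against GM at 25 mM kept its count within 1.5 times under each alternative. At 5 mM the exception was 2789 in place of 4728 within the high-18S cultures, where GM at 5 mM has 1 culture, assumed to vary like the other groups. For glucose in GM, 1 became 0 with a pseudocount of 64, 0 with only the compared arrays, 0 without probe sets named _x_at or _s_at, which leaves out that of Mgll, 0 within the high-18S cultures and 815 with array weights, and 0 to 5 with 1 culture left out. For glucose in DM, 231 became 109 with only the compared arrays and 607 with the block, and 131 to 209 with 1 culture left out. For the interaction, 75 became 41 without a trend, 30 with the replicate number as a block, 333 with array weights, 130 with the batch as a block, 17 within the high-18S cultures and 26 to 104 with 1 culture left out. The replicate number as a block gave 5323, 4292, 1 and 157 for the other comparisons. Replicate numbers were not taken as pairs, since pairs with the same number had a correlation over 0.1 in 3 of 18 cases on MA and 2 of 18 on MB. The 18S batch was not removed from these correlations, so they cannot exclude a pairing.

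Of 115 list tests 42 were called, 14 with an estimated correlation and 19 with the block and an estimated correlation, and the other alternatives with 115 tests gave 37 to 47. Only the compared arrays gave 29 of 92 tests without the interaction, and other filters 37 of 110 or 44 of 125. Medians of lists not among the 42 also changed sign with the block, such as oxidative phosphorylation in GM and glycolysis in the interaction. Among the 42, reversed medians were all in GM: the contractile list at 0.0948 with the block (adjusted p = 0.161, and 0.493 with an estimated correlation as well, range 0.000805 to 0.692), and ribosomal proteins at 0.0347 with quantile normalization, 0.107 with the block and 0.110 within the high-18S cultures (range 3.67e-05 to 0.692). Genes near background had log2 changes that depend on the pseudocount, as for Myog at 25 mM with 6.26 to 8.71.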

Other observations

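Further genes among the 10 largest falls at 5 mM in DM follow as single values, with no test of them as a group. Fgf21, a hormone of the fibroblast growth factor family, fell from 1037 ± 159 at 25 mM to 252 ± 70.5 at 5 mM (SD, n = 3 each, log2 change -1.99 (SE 0.23)), and Il17b, a cytokine, from 542 ± 119 to 113 ± 17.8. Fst, or follistatin, which binds activin and myostatin, fell from 1172 ± 97.8 to 313 ± 16.2, and the related Fstl3 changed by -1.65 (SE 0.19). Nmrk2, a nicotinamide riboside kinase, fell from 1620.5 ± 188 to 239.9 ± 56.3, a log2 change of -2.68 (SE 0.33). In GM these genes read 19.5 ± 10.1 and 7.29 ± 1.98 for Fgf21, 35.8 ± 30.4 and 12.1 ± 0.80 for Fst, and 46.3 ± 19.4 and 36.6 ± 10.5 for Nmrk2, at 25 and 5 mM.

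The cell cycle list was parted by phase after its values at 5 mM against 25 mM in DM were seen, so that the values below give no support to a hypothesis formed from them, although a value seen beforehand can still argue against an explanation. Of 25 measured genes of G2 and mitosis 0 rose and 11 fell, with a median of -0.62 and 25 of 25 below 0. Of 22 measured genes of G1 and S 2 rose and 0 fell, with a median of 0.43 and 3 below 0. The medians differed by -1.04. Within the high-18S and the low-18S cultures they were -0.60 and -0.59 for G2 and mitosis and 0.47 and 0.41 for G1 and S. The low-18S values compare 1 culture with 1.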
